A study of Homo sapiens with 23 samples.

How the data were processed

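Primary human CD4+ T cells, the helper lymphocytes of blood, were isolated from frozen peripheral blood mononuclear cells of 3 donors, per the labels. They were left non-activated with water, activated for 24 h with soluble antibody complexes against CD3 and CD28 in water, or activated while exposed to metformin combined with 2-deoxyglucose. RNA was taken with a column kit from washed and frozen cells, and 400 ng went into a stranded TruSeq kit that selects poly(A) mRNA. The doses of the compounds and the time of their addition are not given in the sources used here.

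The authors deposited 1 table of whole-number read counts per gene symbol for 23 libraries, with no normalization. Per the submitters' processing notes, STAR, featureCounts and the hg38 build were used, and versions, filters and the strand setting of the counting are not given in the sources used here. Counts of genes that overlap on opposite strands, or that share reads with near-identical copies, such as some ribosomal protein, HLA, granzyme and heat shock genes, are therefore uncertain. Each donor and condition had up to 3 libraries, lettered a, b and c in the labels. Nothing in the labels says whether the letters stand for separate cultures or for repeated libraries, so letters were summed within a donor and condition, and the 9 sums, 3 donors in each of 3 conditions, were the replicates.

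Of 26485 gene symbols in the table, 28 had been turned into calendar dates by spreadsheet software, and these held between 0.197% and 0.282% of a library's counts. They were left out because they name no gene. Another 107 sex-linked genes were left out to keep donors' details out of the analysis, which left 26350 symbols, 22072 of them with any count. The table held 0 mitochondrially encoded mRNAs. Symbols were matched to the GENCODE 29 annotation of hg38 for positions, transcript length and GC content, with 23769 matched.

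Genes were kept by edgeR's filterByExpr on the 9 sums, which left 16067. Library sizes were scaled by trimmed mean of M values (TMM). Factors ran from 0.868 to 0.955 in the sums of non-activated cells, from 0.989 to 1.06 in activated cells and from 1.02 to 1.15 in treated cells. Quasi-likelihood negative binomial models with robust spread (edgeR 4.0.16, R 4.3.3) held the donor as a block and the condition. All 9 sums entered 1 fit, and the 3 contrasts between conditions were tested with Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of single genes are from this test. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to a common total, at TMM-scaled library size, as mean ± SD over the 3 donors. Rises and falls are thus relative to the other mRNAs of a library, and the counts give no amount of mRNA per cell.

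Same-donor sums of different conditions deviated together from their condition means. The donor number comes from the labels, and the 9 same-donor correlations over genes ran from 0.311 to 0.627 against −0.394 to −0.0931 for 18 pairs of different donors. Deviations from a condition mean cancel over its donors, so the negative values follow from the positive ones and are no separate evidence of pairing. Fits without this pairing gave 8003, 3921 and 4942 changed genes for activated against non-activated, treated against activated and treated against non-activated cells.

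The lists of genes (pathways, and markers of other blood cells) and the rule for genes named in the text were fixed before the data were examined. The rule takes, for each contrast, the 6 strongest rises and 6 strongest falls among genes past the threshold with a mean log2 CPM of at least 3 and the same sign in all 3 donors, a fixed set of 16 sentinel genes, and the 2 members of each list with the largest absolute change. Other members of a list were named as examples after their values were seen, and results of some single genes are not reported here. Of 813 list entries 798 were found in the table, 27 of them under an older symbol. Each of 35 lists with enough measured members was tested per contrast with camera (limma 3.58.1) at a preset correlation of 0.01, which compares a list with all other genes. The test was repeated with a correlation estimated from the data, which is stricter with 3 donors. Past the threshold were 24, 20 and 17 lists for the 3 contrasts at the preset correlation, and 0, 2 and 0 with the estimated one. The fry test, which asks whether a list moves on balance in one direction, passed 32, 22 and 23.

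To ask how far treatment changes opposed activation changes without reusing the same libraries, activated libraries lettered a were set against non-activated cells to find activation genes at 2-fold or more. Treated cells were then set against activated libraries lettered b and c. Unchanged groups were simulated 10 times under both arrangements to give the covariance that shared activated cells bring with no effect. A simulation with the observed activation and no treatment effect, with calls made anew by the same rule, was added after the share and ratio had been seen.

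The test was checked on simulated counts for treated against activated cells with the real depths over 16067 genes. It recovered 67% of 100 genes changed by 1 on the log2 scale and 99% of 100 genes changed by 2, with 7 false calls among 173. Alternatives were DESeq2 1.42.0, DESeq2 size factors, library totals without TMM, other count filters, a stricter threshold, the fit without donors, single libraries in edgeR and limma voom, 1 library per donor, counts thinned to the smallest sum, each donor left out, and, chosen after the library letters were seen to differ, sums restricted or matched by letter. Trends on GC content and length were smooth terms in mgcv 1.9.3. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.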

Results

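Messenger RNA of human primary CD4+ T cells was counted in 23 libraries from 3 donors under 3 conditions. Non-activated cells in water gave 9 libraries, cells activated for 24 h through the T cell receptor (CD3) and its costimulatory receptor CD28 gave 9, and cells activated with metformin and 2-deoxyglucose gave 5. Metformin is a biguanide that inhibits mitochondrial respiration, and 2-deoxyglucose is a glucose analogue that blocks glycolysis and can be built into glycans. No condition analysed here held either compound alone or either compound on non-activated cells, so each value of treated cells belongs to the combination in activated cells. Whether the compounds were added at or before activation is not in the labels. Total counts per library ran from 13404772 to 57272131 in non-activated cells (median 21727914), from 20692979 to 33132236 in activated cells (median 24920784) and from 9452745 to 18327567 in treated cells (median 16137380). Donors had 3 libraries each in non-activated and activated cells, whereas 1 donor had 3 treated libraries and the others had 1 each. Sums per donor held 71877559 to 93895909 counts in non-activated, 70407242 to 81427929 in activated and 9452745 to 51763446 in treated cells.

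Over 14597 genes, principal component 1 held 53% of the variance and ordered the conditions. Activated libraries scored from −88.3 to −69.1, treated libraries from −30.6 to 4.46 and non-activated libraries from 77.8 to 88.7. Component 2 held 13.7%, and treated libraries lay above all others on it, from 21.98 to 80.56. Activated libraries scored from −50.1 to 11.54 there and non-activated ones from −50.15 to 21.09. Component 3 held 10.6% and separated libraries lettered a from those lettered b and c within each condition. In the 7 combinations of donor and condition with all letters, the difference of a from b and c over genes correlated between combinations at 0.717 to 0.849, against 0.0399 to 0.27 for the difference of b from c. Treated cells had libraries lettered a from 2 donors and libraries lettered b or c from 2 donors.

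**Figure D1:**
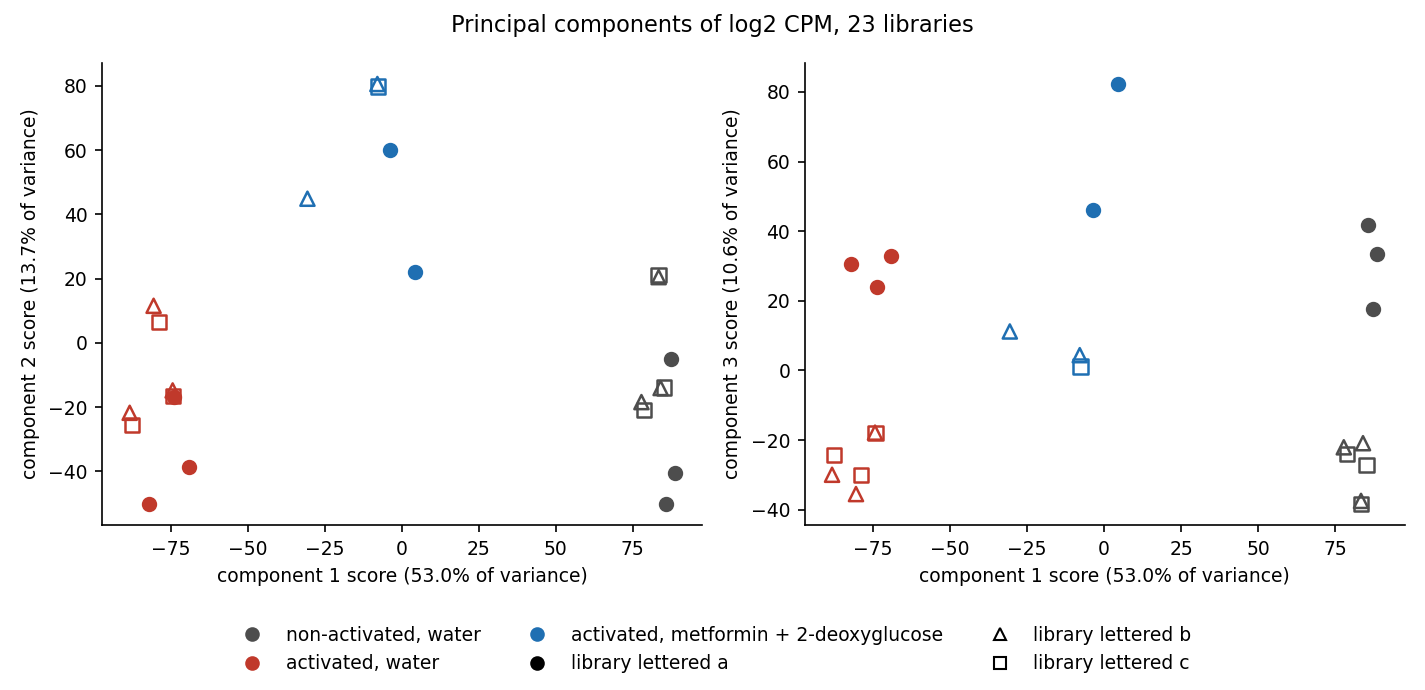
Scores of the 23 libraries on principal component 1 against component 2 (left) and component 3 (right), in score units of log2 CPM over 14597 genes, with colour for the condition and marker for the library letter. Treated libraries lie between −30.6 and 4.46 on component 1, between activated and non-activated ones, and within each condition the libraries lettered a lie above the others on component 3. On component 2 the treated libraries lie from 21.98 to 80.56, above all others.

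The first comparison set cells activated for 24 h without the compounds against non-activated cells. The labels used here give no time in culture for non-activated cells. In comparisons with them, a difference in that time cannot be told apart from activation. Activated cells expressed most of the measured cytokine and chemokine genes above the level of resting cells. The type 1 cytokine IFNG (chromosome 12, 68154768 to 68159747 on hg38) stood at 11.6 ± 5.52 CPM in non-activated and 1964 ± 433 CPM in activated cells (SD, n = 3 donors; log2 change 7.56, SE 0.46, adjusted p = 8.06e-07). The T cell growth factor IL2 (chromosome 4, 122451470 to 122456725) went from 0.521 ± 0.419 to 172 ± 73.1 CPM (log2 change 8.48, SE 0.50, adjusted p = 7.17e-07), and its high-affinity receptor chain IL2RA from 29.9 ± 8.47 to 1603 ± 374 CPM. Genes of resting cells fell, among them KLF2 (chromosome 19, 16324817 to 16327874), a transcription factor of quiescent and recirculating T cells, from 1230.5 ± 462 to 31.4 ± 10.6 CPM, and the glucocorticoid-induced gene TSC22D3 from 3195 ± 275 to 57.5 ± 12.97 CPM. In all, 9688 of 16067 genes changed (60.3%), 4659 upward and 5029 downward, of which 2936 and 3404 by at least 2-fold.

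Among cytokines and chemokines, 23 of 26 measured members rose and 0 fell (median log2 change 6.24, camera adjusted p = 7.10e-35, adjusted p = 0.0536 with an estimated correlation). The strongest rises included IL17F, to 131 ± 106 CPM from 11 counts in all non-activated libraries, and IL9, to 176 ± 86.4 CPM from 20 counts. IL22 rose to 147 ± 42.4 CPM from 0.147 ± 0.0573. With CCL1, which had 0 counts at rest, set at the limit of 3 counts over the group, the list median was again 6.24. Of the T cell activation receptors 13 of 16 rose and 2 fell (median log2 change 1.96, camera adjusted p = 7.26e-10, adjusted p = 0.0536 with an estimated correlation), among them TNFRSF8, the CD30 receptor (chromosome 1, 12063377 to 12144207; log2 change 7.59, SE 0.23). Of the co-inhibitory receptors 8 of 12 rose and 2 fell (median log2 change 1.40, camera adjusted p = 1.13e-04, adjusted p = 0.127 with an estimated correlation), with LAG3 and CD274, the ligand PD-L1, in front. Lineage transcription factors rose in 11 of 15 and fell in 3 (median log2 change 1.03, camera adjusted p = 0.00141, adjusted p = 0.139 with an estimated correlation). Adjusted over the list alone, 24 cytokines rose, and the counts of the other lists in this paragraph were the same. Immediate T cell receptor genes went both ways at 24 h, 8 up and 13 down of 24 (camera adjusted p = 0.0911), with the nuclear receptor NR4A2 and the AP-1 subunit FOSB lower (−5.50 and −5.04 on the log2 scale).

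Biosynthetic and proliferation genes rose together with activation. All 26 measured genes of serine, one-carbon and nucleotide synthesis rose (median log2 change 2.35, camera adjusted p = 5.36e-16, adjusted p = 0.139 with an estimated correlation), among them the serine synthesis enzyme PSAT1, from 4.26 ± 0.902 to 161 ± 83.9 CPM. Of the S phase genes 31 of 33 rose and 0 fell (median log2 change 2.69, camera adjusted p = 3.22e-20, adjusted p = 0.127 with an estimated correlation), and of the G2 and M phase genes 22 of 30 rose and 2 fell (median log2 change 1.65, camera adjusted p = 7.28e-05, adjusted p = 0.331 with an estimated correlation). Ribosome biogenesis and MYC target genes rose in 31 of 36 and fell in 2 (median log2 change 1.40, camera adjusted p = 4.30e-10, adjusted p = 0.186 with an estimated correlation), and the growth regulator MYC itself went from 119.8 ± 45.7 to 411 ± 40.7 CPM. The mRNAs of cytosolic ribosomal proteins fell, relative to other mRNAs, in 49 of 51 and rose in 0 (median log2 change −0.84, camera adjusted p = 2.33e-07, adjusted p = 0.324 with an estimated correlation). Whether their amount per cell fell cannot be told from these counts. Glycolysis genes rose in 14 of 24 and fell in 2 (median log2 change 1.27, camera adjusted p = 5.90e-06, adjusted p = 0.139 with an estimated correlation), with the glycolytic enzyme ENO1 at 404 ± 31.6 CPM at rest and 3451 ± 468 CPM after activation. Nuclear genes of oxidative phosphorylation rose in 48 of 69 and fell in 2 (median log2 change 0.67, camera adjusted p = 2.22e-05, adjusted p = 0.0536 with an estimated correlation). TCA cycle genes rose in 15 of 22 and fell in 1 (median log2 change 0.73, camera adjusted p = 9.81e-04, adjusted p = 0.127 with an estimated correlation). Quiescence and naive T cell genes fell in 21 of 24 and rose in 1 (median log2 change −1.57, camera adjusted p = 9.02e-11, adjusted p = 0.09905 with an estimated correlation). Adjusted over the list alone, 32 S phase, 15 glycolysis and 49 oxidative phosphorylation genes rose.

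Interferon-stimulated genes rose in 20 of 32 and fell in 2 (median log2 change 1.18, camera adjusted p = 6.64e-06, adjusted p = 0.349 with an estimated correlation). Markers of monocytes, which a CD4 isolation can carry along, fell in 11 of 14 (median log2 change −2.56, camera adjusted p = 8.81e-06, adjusted p = 0.142 with an estimated correlation). The median marker stood at 3.55 ± 1.4 CPM in non-activated, 0.637 ± 0.13 CPM in activated and 0.324 ± 0.078 CPM in treated cells, against 370 ± 86, 320 ± 23 and 314 ± 44 CPM for CD4 T cell markers. The number of changed genes was 10229 with libraries matched by letter, 9553 with libraries lettered a and 10872 with those lettered b and c.

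The second comparison asked what the combination of metformin and 2-deoxyglucose changed in activated cells. The cytokine genes were far lower with the compounds, and those of glycolysis, nucleotide synthesis, DNA replication and ribosome production were lower too. IFNG stood at 1964 ± 433 CPM in activated and 10.02 ± 5.38 CPM in treated cells (log2 change −7.80, SE 0.47, adjusted p = 6.56e-06), the latter close to its level at rest. The leukemia inhibitory factor gene LIF, a secreted cytokine (chromosome 22, 30240447 to 30246851) went from 813 ± 215 to 12.6 ± 3.76 CPM (log2 change −6.03, SE 0.20, adjusted p = 4.32e-08), and IL2 from 172 ± 73.1 to 18.7 ± 10.8 CPM (log2 change −3.33, SE 0.39, adjusted p = 2.20e-04). The thioredoxin-interacting gene TXNIP, which limits glucose uptake, rose from 288 ± 80.9 to 1036 ± 295 CPM (log2 change 1.85, SE 0.21, adjusted p = 1.71e-04). In all, 5876 of 16067 genes changed (36.6%), 2677 upward and 3199 downward, of which 1435 and 1704 by at least 2-fold, and 5797 of them moved the same way in all 3 donors. Without donor 3, who gave 3 of the 5 treated libraries, 2484 genes changed, 2469 of them among the 5876. The number was 7502 with libraries matched by letter, 6101 with libraries lettered a and 6215 with those lettered b and c.

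Of 26 cytokines and chemokines 21 fell and 0 rose (median log2 change −3.58, camera adjusted p = 1.24e-41, adjusted p = 0.0368 with an estimated correlation, and 0.0972 with libraries matched by letter). IL9 (chromosome 5, 135892246 to 135895827) had 42366 counts in activated and 13 in treated cells, and IL17F had 32372 and 12. These counts are not scaled for depth. Donor sums held 70407242 to 81427929 counts in activated and 9452745 to 51763446 in treated cells. IL10 fell from 192 ± 11.1 to 1.21 ± 0.617 CPM and TNF from 426 ± 87.9 to 54.1 ± 20.5 CPM. With IL31, which had 0 counts in treated cells, set at the limit of 3 counts over the group, the list median stayed at −3.58. Activation receptors fell in 11 of 16 and rose in 1 (median log2 change −1.10, camera adjusted p = 2.90e-10, adjusted p = 0.0901 with an estimated correlation). TNFRSF8 went from 103 ± 11.2 to 1.595 ± 0.257 CPM and IL2RA from 1603 ± 374 to 296 ± 162 CPM. Co-inhibitory receptors fell in 6 of 12 and rose in 2 (median log2 change −0.56, camera adjusted p = 0.00397, adjusted p = 0.166 with an estimated correlation), with the checkpoint receptor CTLA4 at 595 ± 46.8 CPM in activated and 60.3 ± 2.41 CPM in treated cells. Lineage transcription factors fell in 7 of 15 and rose in 2 (median log2 change −0.28, camera adjusted p = 0.00124, adjusted p = 0.119 with an estimated correlation), with the type 1 factor TBX21 among the falls (log2 change −2.40, SE 0.36). With p adjusted over the list alone, 12 activation receptors fell and 2 rose. Of the cytotoxic granule genes 5 of 12 fell and 2 rose (camera adjusted p = 0.197), among them the protease gene GZMB, from 1618 ± 633 to 42.4 ± 20.2 CPM.

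Glycolysis genes fell in 18 of 24 and rose in 0 (median log2 change −1.27, camera adjusted p = 4.34e-12, adjusted p = 0.118 with an estimated correlation). Lactate dehydrogenase LDHA went from 1477 ± 331 to 319.7 ± 164 CPM, hexokinase HK2, which phosphorylates glucose and 2-deoxyglucose, from 174 ± 33.8 to 43.7 ± 20.6 CPM, and ENO1 from 3451 ± 468 to 1171 ± 333 CPM. Nuclear oxidative phosphorylation genes fell in 35 of 69 and rose in 0 (median log2 change −0.49, camera adjusted p = 5.37e-07, adjusted p = 0.0438 with an estimated correlation, and 0.169 with libraries matched by letter). TCA cycle genes fell in 9 and rose in 1 of 22 (median log2 change −0.44, camera adjusted p = 0.0147, adjusted p = 0.177 with an estimated correlation), and this list test was lost without donor 3 (adjusted p = 0.0582). Serine, one-carbon and nucleotide synthesis genes fell in 20 of 26 and rose in 0 (median log2 change −1.05, camera adjusted p = 4.56e-09, adjusted p = 0.217 with an estimated correlation), and fatty acid synthesis genes fell in 13 of 16 and rose in 0 (median log2 change −0.84, camera adjusted p = 4.63e-05, adjusted p = 0.166 with an estimated correlation). Adjusted over the list alone, 42 oxidative phosphorylation, 13 TCA cycle, 21 serine and nucleotide and 15 fatty acid synthesis genes fell.

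Proliferation genes fell as well. S phase genes fell in 32 of 33 and rose in 0 (median log2 change −2.39, camera adjusted p = 1.67e-40, adjusted p = 0.118 with an estimated correlation), with the replication factor MCM10 at 29.3 ± 8.27 CPM in activated and 0.657 ± 0.5195 CPM in treated cells. G2 and M phase genes fell in 23 of 30 and rose in 0 (median log2 change −1.76, camera adjusted p = 7.05e-11, adjusted p = 0.233 with an estimated correlation), and the proliferation marker MKI67 went from 12.1 ± 5.16 to 2.04 ± 0.8601 CPM. Ribosome biogenesis and MYC target genes fell in 35 of 36 and rose in 0 (median log2 change −1.18, camera adjusted p = 2.29e-18, adjusted p = 0.119 with an estimated correlation), and MYC fell by 1.07 on the log2 scale (SE 0.20, adjusted p = 0.00221). When adjusted over the list alone, 36 of them fell. Heat shock protein genes fell in 10 of 16 and rose in 0 (median log2 change −1.30, camera adjusted p = 1.40e-05, adjusted p = 0.119 with an estimated correlation), for example the chaperone HSP90AA1 from 2163 ± 149.8 to 549.9 ± 223 CPM.

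Quiescence and naive genes rose in 16 of 24 and fell in 1 (median log2 change 0.77, camera adjusted p = 3.20e-07, adjusted p = 0.118 with an estimated correlation). KLF2 reached 211 ± 129.9 CPM and the naive T cell factor TCF7 666 ± 129 CPM, from 195 ± 84.5 CPM in activated cells. Ribosomal protein mRNAs rose in 19 of 51 and fell in 0 (median log2 change 0.41, camera adjusted p = 1.20e-04, adjusted p = 0.578 with an estimated correlation). The largest rise among named genes was that of GNAO1, a G protein alpha subunit (chromosome 16, 56191347 to 56357457), from 4.27 ± 3.22 to 110.5 ± 78.4 CPM (log2 change 4.76, SE 0.21, adjusted p = 4.83e-07). LY9, a receptor of the SLAM family (chromosome 1, 160796074 to 160828261), rose from 9.32 ± 2.75 to 91.6 ± 55.97 CPM.

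Stress-response genes of the integrated stress response split, with 8 of 29 up and 6 down (camera adjusted p = 0.542). TRIB3, a pseudokinase induced by that response (chromosome 20, 362835 to 397559), rose from 40.5 ± 10.7 to 144 ± 26.05 CPM (log2 change 1.84, SE 0.22, adjusted p = 2.67e-04), and the stress-induced factor DDIT3 rose from 18.8 ± 1.28 to 88.5 ± 36.5 CPM. The asparagine synthetase gene ASNS stood at 145 ± 54.5 and 111 ± 44.2 CPM (adjusted p = 0.136). Endoplasmic reticulum chaperone genes rose in 4 and fell in 3 of 30 (camera adjusted p = 0.363), and the chaperone HSPA5 stood at 965 ± 89.6 and 1153 ± 219.8 CPM (adjusted p = 0.239). N-glycosylation genes rose in 1 and fell in 8 of 37 (camera adjusted p = 0.326). Hypoxia-response genes rose in 3 and fell in 7 of 19 (camera adjusted p = 0.281). With p adjusted over the list alone, 7 integrated stress response genes fell, and 4 endoplasmic reticulum genes rose and 1 fell. Of the p53 targets, 10 rose and 2 fell of 19 (median log2 change 0.57, camera adjusted p = 0.0122, adjusted p = 0.166 with an estimated correlation). Interferon-stimulated genes rose in 1 and fell in 8 of 32 (median log2 change −0.54, camera adjusted p = 0.0265, adjusted p = 0.735 with an estimated correlation), and cholesterol synthesis genes rose in 1 and fell in 8 of 24 (median log2 change −0.27, camera adjusted p = 0.0481, adjusted p = 0.359 with an estimated correlation). Both of these list tests were lost with libraries matched by letter (adjusted p = 0.103 and 0.0709). Monocyte markers rose in 3 and fell in 6 of 14 in this comparison (camera adjusted p = 0.6298).

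**Figure D2:**
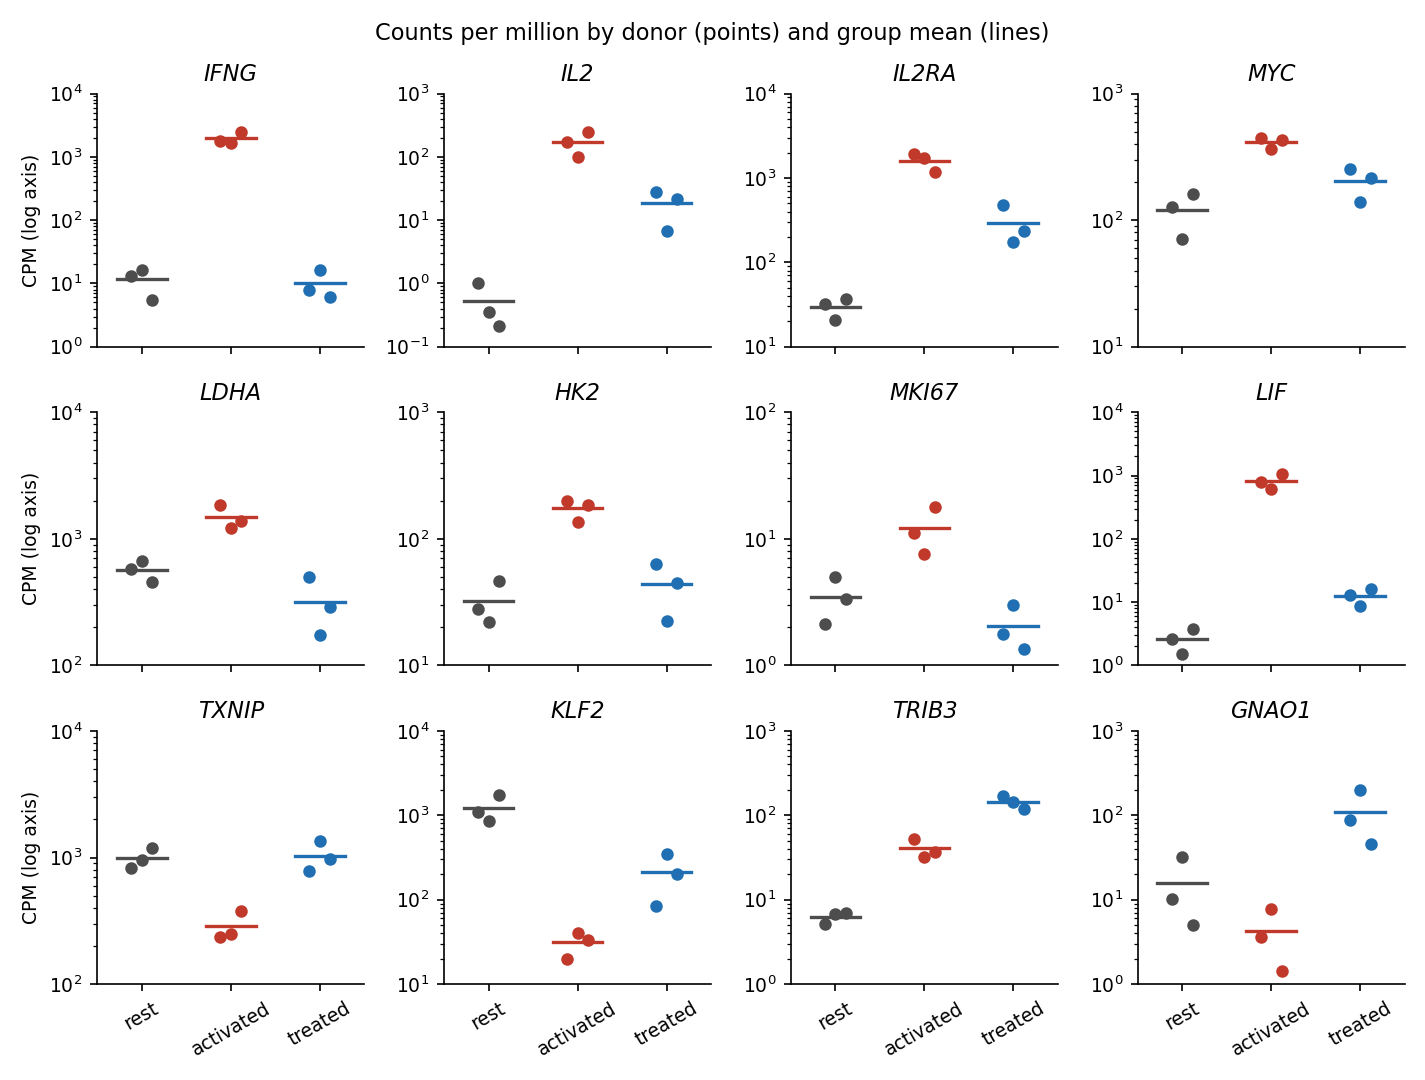
CPM of 12 genes on log axes in non-activated (rest), activated and treated cells, with 1 point per donor and a line at the mean of 3 donors. IFNG stands at 11.6, 1964 and 10.02 CPM on average in the 3 conditions, and TRIB3 at 6.3, 40.5 and 144 CPM.

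The third comparison asked how far treated cells stood from non-activated cells. In treated cells 6799 of 16067 genes differed from rest (42.3%), 3201 higher and 3598 lower. They held more IL2RA (296 ± 162 against 29.9 ± 8.47 CPM, log2 change 3.21, SE 0.30, adjusted p = 3.11e-05). The ubiquitin-like gene UBD (chromosome 6, 29555515 to 29559925) stood at 24.98 ± 8.46 CPM, against 4 counts in all non-activated libraries, and the T cell attracting chemokine CXCL9 at 53.4 ± 29.5 against 0.192 ± 0.171 CPM. They held less FOSB (28.03 ± 16.4 against 2758 ± 513 CPM) and less KLF2 (211 ± 129.9 against 1230.5 ± 462 CPM). IFNG did not pass the test (log2 change −0.24, SE 0.36, adjusted p = 0.625). The number of changed genes was 4049 without donor 1 and 3749 without donor 3, and 8215 with libraries matched by letter, 6196 with those lettered a and 7661 with those lettered b and c. With library totals in place of TMM, 65.5% of changed genes were higher in place of 47.1%, and the median of all genes moved from −0.0301 to 0.220 on the log2 scale.

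Cytokines and chemokines were higher than at rest in 14 of 26 and lower in 0 (median log2 change 1.63, camera adjusted p = 8.10e-09, adjusted p = 0.221 with an estimated correlation), with the same median when IL31 and CCL1, at 0 counts in a group, were set at the limit of 3 counts. Activation receptors were higher in 9 of 16 and lower in 3 (median log2 change 1.48, camera adjusted p = 0.00102, adjusted p = 0.221 with an estimated correlation). Interferon-stimulated genes were higher in 16 of 32 and lower in 2 (median log2 change 0.88, camera adjusted p = 2.78e-05, adjusted p = 0.576 with an estimated correlation), and this list test was lost without donor 3 (adjusted p = 0.126). Integrated stress response genes were higher in 20 of 29 and lower in 4 (median log2 change 1.22, camera adjusted p = 6.07e-09, adjusted p = 0.221 with an estimated correlation), for example the tryptophan tRNA synthetase WARS, at 758 ± 98.3 against 47.6 ± 6.45 CPM. Endoplasmic reticulum chaperone genes were higher in 19 of 30 and lower in 0 (median log2 change 0.77, camera adjusted p = 2.53e-08, adjusted p = 0.259 with an estimated correlation), for example the disulfide isomerase PDIA4, at 329 ± 61.03 against 50.9 ± 6.07 CPM. Serine, one-carbon and nucleotide synthesis genes were higher in 17 of 26 and lower in 1 (median log2 change 1.26, camera adjusted p = 6.07e-09, adjusted p = 0.2704 with an estimated correlation), with PSAT1 at 124 ± 70.2 CPM. Pentose phosphate and NRF2 genes were higher in 12 of 18 and lower in 1 (median log2 change 0.66, camera adjusted p = 0.00359, adjusted p = 0.291 with an estimated correlation), and N-glycosylation genes in 17 and 3 of 37 (median log2 change 0.50, camera adjusted p = 0.00819, adjusted p = 0.466 with an estimated correlation). Activation without the compounds raised such lists too. Integrated stress response genes rose in 18 and fell in 4 of 29 (median log2 change 1.22, camera adjusted p = 5.59e-05), and endoplasmic reticulum chaperone genes in 17 and 1 of 30 (0.66, 4.36e-04). Pentose phosphate and NRF2 genes rose in 13 and fell in 2 of 18 (1.28, 0.002), and N-glycosylation genes in 21 and 5 of 37 (0.73, 0.00477). With an estimated correlation the adjusted p ran from 0.139 to 0.324.

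Glycolysis genes stood on both sides of the resting level, 6 higher and 6 lower of 24 (camera adjusted p = 0.694), as did S phase genes, 9 higher and 7 lower of 33 (camera adjusted p = 0.4801), and oxidative phosphorylation genes, 9 higher and 7 lower of 69 (camera adjusted p = 0.289). Quiescence genes were lower in 16 of 24 and higher in 1 (median log2 change −0.84, camera adjusted p = 1.06e-06, adjusted p = 0.221 with an estimated correlation), and immediate T cell receptor genes lower in 14 of 24 and higher in 5 (median log2 change −0.98, camera adjusted p = 7.60e-06, adjusted p = 0.221 with an estimated correlation). Heat shock protein genes were lower in 8 of 16 and higher in 0 (median log2 change −0.70, camera adjusted p = 0.00208, adjusted p = 0.2704 with an estimated correlation). Monocyte markers were lower in 11 of 14 (median log2 change −2.83, camera adjusted p = 2.19e-08, adjusted p = 0.2704 with an estimated correlation). Adjusted over the list alone, 15 cytokines, 11 activation receptors, 13 pentose phosphate and NRF2, 20 N-glycosylation and 7 glycolysis genes were higher. Lower on that basis were 4 activation receptors, 1 endoplasmic reticulum, 6 N-glycosylation and 10 heat shock genes and 14 monocyte markers.

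**Figure D3:**
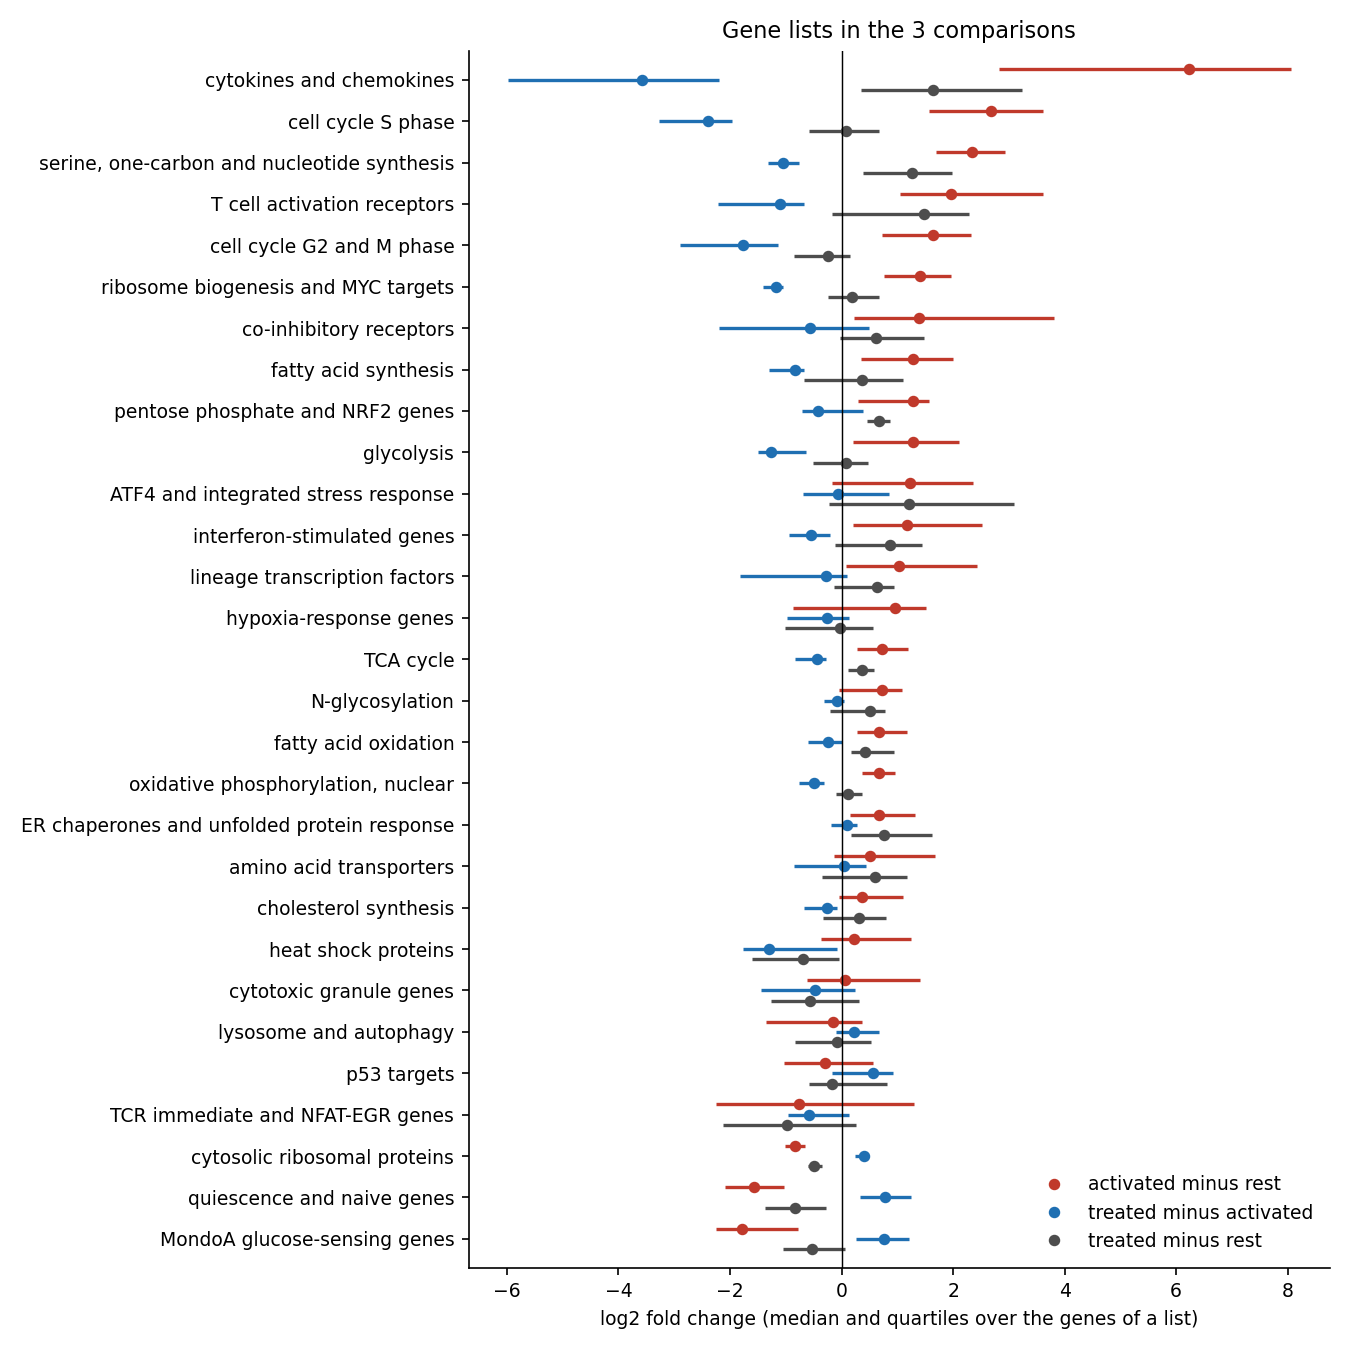
Median (point) and quartiles (bar) of the log2 fold change over the measured members of 29 pathway lists in the 3 contrasts. Cytokines and chemokines have medians of 6.24 for activated against non-activated, −3.58 for treated against activated and 1.63 for treated against non-activated cells.

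The last comparison asked how the treatment changes lay to the activation changes. More of the genes that rose with activation fell than rose with treatment, and the reverse held for genes that fell with activation, among them IFNG, LIF, MCM10 and ENO1 on one side and KLF2, TCF7 and TXNIP on the other. Of the 4659 genes that rose with activation, 2360 fell with treatment (50.6%) and 111 rose further, where independent lists would share 928 and 776. Of the 5029 that fell, 1823 rose with treatment (36.2%) and 171 fell further, where independent lists would share 838 and 1001. Among the 2360, 798 were still above rest, 1447 were not apart from rest by the test and 115 were below it. Among the 1823, 553 were still below rest, 1194 were not apart from it and 76 were above it. Without donor 3 the first overlap held 1100 genes and the other 640, and without donor 1 the other held 1113. The 798 and 553 became 321 and 241 without donor 1, 226 and 133 without donor 3, and 474 and 244 without the donor block. They became 1290 and 987 with libraries matched by letter and 1457 and 1083 with the 23 libraries separate in edgeR. With donor and batch blocks in the 23 libraries they were 2316 and 1827, and the overlaps themselves 4066 and 3734.

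Both contrasts use the activated cells, so their errors run against each other. In 10 simulations of unchanged groups the highest overlap was 0 genes for rises that fell and 1 for falls that rose, with edgeR's test making at most 9 calls in either contrast. With so few calls an overlap near 0 was given, so this value does not measure what the shared cells add to the overlaps. With activated libraries split by letter between the contrasts, the overlaps were 2194 and 1833 genes, against 1075 and 1064 for independent lists. Over the 5683 genes that changed by at least 2-fold with activation in that split, 80.01% moved the opposite way with treatment (mean of single donors 78.3%, SD 6.49, n = 3). The median ratio of the treatment change to the activation change was −0.367 (mean of single donors −0.355, SD 0.0383). In 10 simulations with activation as observed and treated cells unchanged from activated ones, the same rule picked 5101 to 5230 genes, of which 55% on average (at most 56.1%) moved the opposite way, with a median ratio of −0.0181 on average (at the most negative −0.022). With treated as well as activated libraries limited to letters b and c in that contrast, which leaves 2 donors with treated cells, the share was 84.6% and the ratio −0.401. In the main split the ratio was −0.393 for 2832 genes that rose and −0.337 for 2851 that fell. The covariance of the fold changes over genes was −0.821 in the split and −0.0335 in simulated unchanged groups, a difference of −0.788. Simulated libraries held no difference between letters, whereas real libraries lettered a differed from b and c by an SD of 0.508 to 0.727 over genes. The simulated shares, ratios and covariances therefore leave out what a letter difference does to the real ones. In the main split such a difference enters both contrasts with the same sign. Libraries lettered a sit on the activated side of the first and, for 2 donors, on the treated side of the second. A letter difference that all conditions share thus works against opposite moves there, by an amount that was not tested. Genes are not independent replicates, and the labels do not say whether the split libraries come from separate cultures, so a deviation they share would stay in both contrasts.

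**Figure D4:**
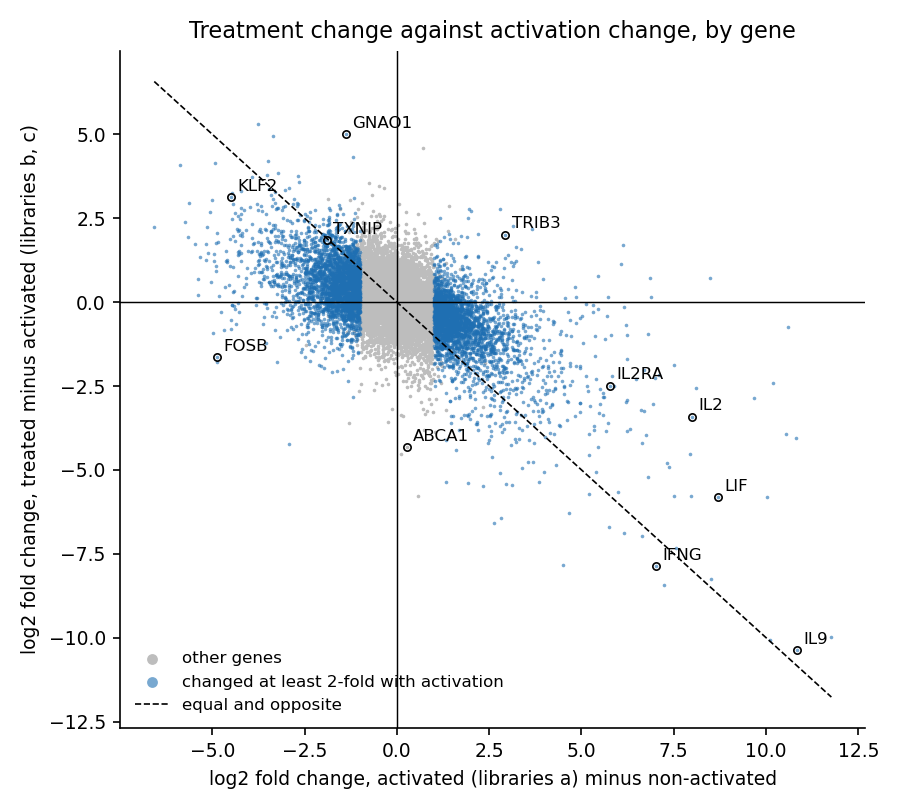
Log2 fold change of treated against activated cells (activated libraries lettered b and c, vertical axis) over that of activated against non-activated cells (activated libraries lettered a, horizontal axis), with 1 point per gene. Of the 5683 genes changed by at least 2-fold with activation, 80.01% lie on opposite sides of 0 on the axes.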

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

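Sums matched or restricted by letter and the fit with donor and batch blocks were chosen after seeing the data, and the other settings, activated libraries lettered b or c for the calls included, before. Activated against non-activated cells gave between 7002 and 10077 changed genes with a donor left out, and no alternative moved the 9688 by over 1.5 times. Treated against activated cells gave 2484 to 5948 with a donor left out, the lowest without donor 3, 10541 in the 23 libraries with donor and batch blocks, and 3234 at an adjusted p of 0.01, against 5876. Treated against non-activated cells gave 3749 to 7592 with a donor left out, the lowest without donor 3 and 4049 without donor 1, 10888 with donor and batch blocks and 4127 at 0.01, against 6799. A stricter threshold lowers such counts by construction, whereas of the fits with a donor left out, that without donor 2 gave the highest counts. The share of activation genes opposed by treatment was 75.6% to 84.4% with a donor left out, 86.9% without the split of activated libraries, 86.5% for activation at 4-fold and 73.3% at any fold, against 80.01%. The median ratio was −0.392 to −0.315 with a donor left out, the weakest without donor 3, −0.409 and −0.438 with activated libraries lettered b or c for the calls and −0.462 without the split, against −0.367. Without the split both contrasts share all activated libraries. In the simulations with treated cells unchanged, sharing added little: 55% and a ratio of −0.0181 with the split, 55.5% and −0.0199 without. With activated libraries lettered b or c for the calls and no sharing, the shares were 84.1% and 86.1%. The values thus depend on which activated libraries make the calls. In the main split a letter difference shared by all conditions works against opposite moves, and its part in these differences was not tested. No named gene or list that passed its test changed sign under a setting run for it, while values that missed the test could, as IFNG in treated against non-activated cells did, from −0.661 to 0.0331 on the log2 scale.

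DESeq2 called 9716, 6353 and 7167 genes for the 3 contrasts and counts thinned to the smallest sum 7680, 4893 and 5447. The thinned fit tested 12994 genes in place of 16067, so depth limited the number of calls at least in part through the number of genes tested. Library totals in place of TMM turned the balance of calls, from 2677 higher and 3199 lower to 3169 and 2711 for treated against activated cells and from 4659 and 5029 to 5387 and 4236 for activated against non-activated cells, with the median of all genes moving from −0.00118 to 0.0852 and from −0.0665 to 0.0975 on the log2 scale. Without the donor block 8003, 3921 and 4942 genes were called, the genes higher or lower in treated cells than in both others fell from 659 and 731 to 321 and 437, and genes that fell with activation and rose with treatment from 1823 to 1071. Among genes named by the rule, that fit lost calls of CD69, ARRDC4, EGLN3, FADS2, GZMA, GZMH, IFIT3, LDHA, MYC, NDUFC2, RSAD2, S1PR5, SCD and SRXN1 in at least 1 contrast (for LDHA and MYC, treated against non-activated). Among lists it lost the treatment calls of MondoA glucose-sensing, cholesterol synthesis and interferon-stimulated genes (adjusted p = 0.0658, 0.0753 and 0.0518) and gained lysosome and autophagy genes with activation and treatment (0.029 and 0.046). It changed no other call of a list or of a gene named by the rule, and genes named outside the rule were not compared one by one. TMM without mitochondrial genes was not run, because the table holds 0 of them.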

Other observations

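The tests of enrichment in the paragraphs here and the monocyte, letter-depth, letter-mark and fold-at-equal-depth tests were chosen after the values they bear on had been seen, and the settings with libraries matched by letter or with donor and batch blocks after the letters were seen to differ.

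In treated cells 659 genes were higher and 731 lower than in both other conditions. With library totals in place of TMM the numbers were 1076 and 452, so their balance depends on the scaling. Integrated stress response genes made up 6 of the 659 out of 29 measured (TRIB3, CEBPG, SLC7A11, GDF15, AARS and XPOT; one-sided hypergeometric test over the 35 lists and 2 shorter ones, adjusted p = 0.0182), and p53 targets 5 out of 19 (ZMAT3, DDB2, FDXR, PHLDA3 and CCNG1; adjusted p = 0.0182). This test, also used for the lower genes, takes genes as independent, and no version that allows for their correlation was run. As whole lists, for treated against activated cells, the integrated stress response had a camera adjusted p = 0.542 (adjusted p = 0.782 with an estimated correlation) and p53 targets 0.0122 (adjusted p = 0.166). Against non-activated cells they had 6.07e-09 (adjusted p = 0.221) and 0.643 (adjusted p = 0.766). For activated against non-activated cells they had 5.59e-05 (adjusted p = 0.139), upward, and 0.230 (adjusted p = 0.349), downward. The largest rises against both belonged to GNAO1 (15.8, 4.27 and 110 CPM in non-activated, activated and treated cells), the membrane progestin receptor PAQR8 (10.8, 10.4 and 46.8 CPM) and the collagen-binding integrin ITGA1 (5.2, 4.09 and 22.1 CPM). The ATP-gated channel P2RX7 stood at 11.4, 19.5 and 74 CPM.

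The 731 lower genes were 391 without donor 1, 235 without donor 3, 437 without the donor block and 1728 with donor and batch blocks. Among the 731 were 5 of 16 heat shock genes (HSPA1A, HSPH1, HSP90AA1, DNAJA1 and CHORDC1; adjusted p = 0.00733), 7 of 33 S phase genes (adjusted p = 0.00733), 5 of 24 immediate T cell receptor genes (FOS, FOSB, FOSL1, JUNB and NFKBIA; adjusted p = 0.0294), 5 of 24 glycolysis genes (SLC2A1, PFKFB3, LDHA, SLC16A1 and SLC16A3; adjusted p = 0.0294), 6 of 36 ribosome biogenesis genes (adjusted p = 0.0325) and 5 of 14 monocyte markers (adjusted p = 0.00733). Of these glycolysis genes, the calls of SLC2A1 and LDHA against rest were lost when a donor was left out. The cholesterol exporter ABCA1 went from 29 and 44.3 CPM in non-activated and activated cells to 2.31 CPM, and the AP-1 subunit FOSL2 from 374 and 353 to 55.2 CPM. Markers of B cells, natural killer cells and platelets, with medians of 1.2, 0.713 and 0.612 CPM at rest, were at 0.572, 0.487 and 0.0739 CPM in treated cells. Markers of CD8 T cells, plasmacytoid dendritic and erythroid cells were at 2.66, 1.69 and 0.0515 CPM there.

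Technical sources were weighed for the 659 genes. With trends on GC content and length removed, 93.8% of them were still higher than in both others, and with libraries matched by letter 93.5% were, which argues against either as the whole source. At counts thinned to the smallest sum, 73.1% were still called and 77 were not measured, so the number called cannot be told apart from an effect of depth. The median change against activated cells over the 582 measured genes was 1.08 at equal depth and 1.05 at full depth. Thinning the same counts keeps a gene's fold on average, so this agreement was given and does not test depth as the source of the fold. The number depends on donors, scaling, GC and length trends and the handling of letters: 321 genes without donor 1, 197 without donor 3 and 321 without the donor block, but 1276 with GC and length trends removed, 1076 with library totals, 1031 with libraries matched by letter, 1290 and 1154 with the 23 libraries separate in edgeR and limma voom, and 2120 with donor and batch blocks. A response to the combination that is separate from blunted activation may underlie them, as a hypothesis found on the same data that the checks here used. It was not tested, because no condition analysed here held either compound alone or either compound on non-activated cells.

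A separate pattern was that 16 of 32 interferon-stimulated genes were above rest in treated cells while IFNG was not (adjusted p = 0.625, with a range of 0.235 to 0.993 over the alternatives run for it). A larger share of monocyte reads than at rest is argued against, because the median of the monocyte markers changed by −2.83 on the log2 scale from rest to treated cells. The markers do not measure interferon-stimulated genes within monocytes that remained, so that source was not tested. At equal depth 93.8% of the 16 were still higher, and with libraries matched by letter 87.5% were. Without donor 3, 12 of the 16 were. A candidate explanation is an interferon response early in activation that outlasted the IFNG transcript or came from another interferon, and no time point before 24 h was analysed here to test it.

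The libraries lettered a stood apart from those lettered b and c in every combination of donor and condition that held all letters. Smooth trends on GC content and transcript length explained 71.1% of the variance over genes of the mean difference, consistent with a technical difference in how those libraries were made or sequenced. Depth as the whole source is argued against: in 4 of the 7 combinations the library lettered a lay between the others in depth, yet its differences from the shallower and from the deeper library both ran the way of the mean difference in the other combinations, with a lowest correlation of 0.781. All 8 libraries lettered a carried a label that calls them clean and 0 of the 15 others did, so cleaning of the files and another batch difference cannot be told apart.

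Other splits of the 6 donor sums of a comparison into groups of 3 number 10 with the real one, too few for a share under 0.05. In fits to those 6 sums with the donor as a block, edgeR called 10346, 6256 and 5149 genes for the real splits of activated against non-activated, treated against activated and treated against non-activated cells, and as many in 1 of 10 splits, the real one, each time. The highest other split gave 0 calls in each. Every other split mixes both conditions within its groups, which puts the condition difference into the residual spread. Few calls there were given by the design and do not measure false calls. At an unadjusted p under 0.05 the highest other splits had 48, 797 and 506 genes, and no other tool was run on them. The splits that part all 3 donor pairs, 4 with the real one, also gave 0 calls apart from it. Fits without the donor block on all 9 sums gave 8003, 3921 and 4942 calls.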
